A study of Homo sapiens with 4 samples.

How the data were processed

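The study measured gene expression on 4 single-colour chemiluminescence arrays, 1 per RNA sample. Total RNA came from MCF7 cells, an established estrogen receptor positive human breast carcinoma line. The cells carried a tet-off regulator (a transactivator that doxycycline switches off) and an empty response plasmid. Per the labels, 2 samples were grown with doxycycline at 80 ng/ml for 12 days and 2 were grown without it. Per the labels' protocols, cRNA was labelled with digoxigenin before hybridization. The series text names independent clones, but no label ties an array to a clone, so p-values here measure only the spread between these samples.

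Each array came with its own deposited file, which gave 32878 probes with an identifier, a signal intensity, a signal-to-noise score and a quality flag. Per the file headers the intensity columns are raw signals. Some deposited intensities lay below 0 (16 to 34 probes per array), as values do after subtraction of background; that step itself is not given in the sources used here. The signal-to-noise score is the authors' deposited measure of a spot against its own array, and the meaning of the flag codes is not given in the sources used here. The series value table held a further deposited intensity column for each array. Its columns for 3 arrays were quantile normalized: sorted, they equalled the mean of the 4 sorted raw columns. For that mean the value-table column of doxycycline replicate 2 was taken as its raw column, and with its own-file column in that place the 3 columns differed from the mean by a median of 3.25%. The column that its own file calls raw had the normalized distribution (median difference 0% from the mean of the sorted raw columns), and its value-table column differed from that mean by 13.5%. R 2.3.1 is named per the submitters' processing notes. Its role, the scanner software and the annotation release are not given in the sources used here.

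Most probes could not be named. Of the 32878 probes, 32396 carried an hCG identifier (a gene number of the Celera genome annotation), 219 a RefSeq transcript accession and 263 another identifier. Identifiers were matched, without version, to the transcripts and synonyms of NCBI RefSeq's gene table for GRCh38.p14. The match gave 1 symbol for 129 RefSeq and 13 hCG probes, 142 in all or 0.432% of probes, and no probe had several symbols. No position is printed, because the build behind the probes is not given in the sources used here. The 33 gene lists fixed before the data were examined (stress response, mitochondrial, estrogen response, cell cycle, cell type markers and others) held 1 nameable gene on the array in all, the histone gene H4C14. A list needed 5 tested members, so none of these lists was tested. None of the 25 genes fixed by name could be matched to a probe.

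Intensities from the 4 own files were quantile normalized (limma 3.58.1 in R 4.3.3), set to a floor at the 1st percentile (157.2 units) and turned to log2. Quantile normalization uses only ranks within an array and the mean distribution, so that column entered with its ranks intact. No further background correction was applied. A probe counted as detected on an array at a signal-to-noise score of at least 3 with a flag below 5000. Detection in this sense does not show that the signal came from the named transcript. The 21167 probes detected on at least 2 of the 4 arrays were tested, and no probe was marked as a control in the files. The floor applied to 49 values of tested probes. Doxycycline was compared with untreated by limma (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. The number of arrays limits the precision, and an exact permutation test of 2 arrays against 2 cannot go below 0.333. Where a probe was not detected on any array of a group, the fold was taken against the higher of its own signal and the lowest detected signal on each array. For the 5 nameable genes concerned the own signal was the higher, so the fold is that of the group means. It carries their noise and is not a lower limit.

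A rule fixed at the same time as the lists chose the named genes. In each direction it took up to 12 genes past the threshold whose groups did not overlap, by size of change. Places left empty went to genes with the smallest unadjusted p among those with groups that did not overlap and a log2 change of at least 1, said not to pass. Up to 4 genes per direction not detected on any array of 1 group but detected on both of the other were added, by the size of that fold. Members of lists that were tested and the 25 fixed genes would have followed. The change gave GTF2IRD2, KRTAP19-7, FAM72D and IFNE, none past the threshold. Detection in only 1 group gave 5 genes, GTF2IRD2, KRTAP19-7, IFNE, MMP23B and TET3. Because so few probes had names, the other nameable genes with an unadjusted p under 0.05 are given too, as are a few abundant genes. These were chosen after their values were seen. A gene with several probes was represented by the probe with the highest mean signal.

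The limma step was tested on simulated data for this comparison with 21167 probes and real means. Variances were drawn from a fitted prior that depends on mean signal, which the main test does not use. The 200 changed probes were drawn from those detected on all 4 arrays. At an adjusted p under 0.05 it recovered 0 of 50 probes changed by 1 on the log2 scale, 44 of 50 changed by 2 and 48 of 50 changed by 4. The share of unchanged probes with an unadjusted p under 0.05 was 5.12%, and 13 unchanged probes passed the adjusted threshold. With the prior that depends on mean signal, 21 of 50 probes changed by 1 were recovered. In the data 5012 probes had an unadjusted p under 0.05. Recovery after adjustment depends on the share of changed probes, so these counts do not give the power in the data. The alternatives tried were a replicate block, median scaling, the value table, normexp background correction with offset 50, other detection filters, limma-trend (a variance prior that depends on mean signal), a plain two-sample test, a minimum change and leaving out each array. Slide or scan date as a block was not run, because the files have no such column.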

Results

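The data comprised 4 expression arrays of MCF7 tet-off cells carrying an empty response plasmid, 2 from cells kept for 12 days in doxycycline at 80 ng/ml and 2 from untreated cells. Doxycycline is a tetracycline antibiotic that binds metal ions and blocks mitochondrial ribosomes, and it is the switch of the tet-off system. With no transgene present, the comparison addresses the response of this cell system to the drug, in which an effect of the drug itself and the loss of the regulator's activity are not separated. Detected probes numbered 20710 and 20168 on the doxycycline arrays and 20496 and 20973 on the untreated arrays, which was 61.3% to 63.8% of the 32878 probes. The median raw signal was 3149 and 2733 in doxycycline replicates 1 and 2 and 3230 and 3980 in untreated replicates 1 and 2. For doxycycline replicate 2 the value-table column was taken as raw, because the column headed raw in its own file had the distribution of normalized values.

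**Figure D1:**
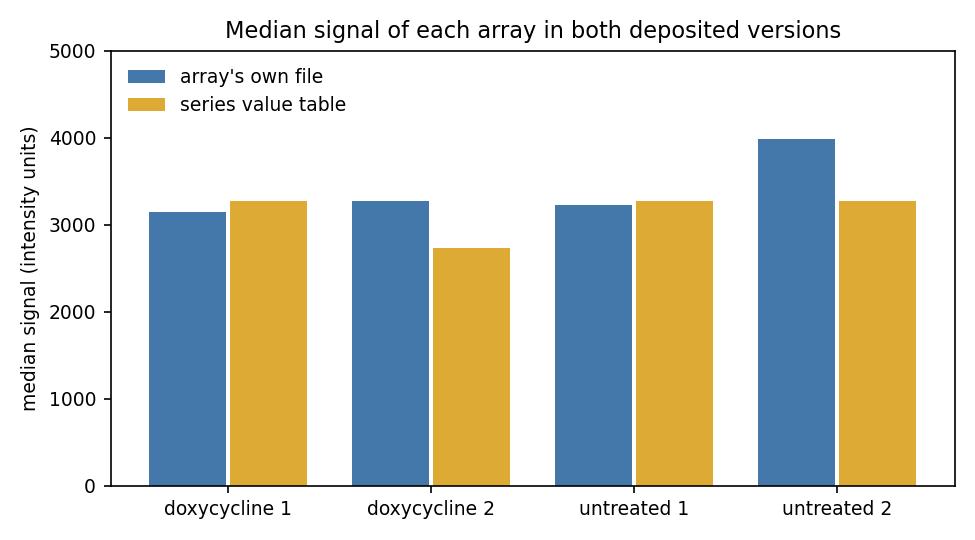
Median signal of the 32878 probes (linear intensity units, axis from 0) for each of the 4 arrays, in the array's own file (blue) and in the series value table (yellow). The deposited table gives 3 arrays the median 3273, while doxycycline replicate 2 has that median in its own file and stands at 2733 there.

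The arrays grouped by treatment. Over the 21167 tested probes the Pearson correlation of log2 signals across probes was 0.985 between the doxycycline replicates and 0.988 between the untreated replicates, against 0.972 to 0.976 for the 4 pairs from different treatments. The median absolute log2 difference was 0.202 and 0.196 within the treatments and 0.296 to 0.330 between them. Probes are not independent replicates, and no test was made of these values.

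The comparison of doxycycline with untreated cells is given first for the genes that could be named. Of these, GTF2IRD2, FAM72D, ZDHHC11 and RAC3 had the smallest p-values. GTF2IRD2, a gene of the general transcription factor TFII-I family, was at 14.45 ± 0.05 on the log2 scale in doxycycline (SD, n = 2) and 12.98 ± 0.02 in untreated cells (SD, n = 2). Its signal was 2.77-fold higher in doxycycline, with a limma adjusted p of 0.0794. It did not count as detected on either untreated array. Its untreated signal still lay above that of ZDHHC11 (11.87), which was detected on all 4 arrays. The missing detection thus does not show that the transcript was absent. FAM72D, a member of a family of near-identical proliferation-associated genes, was at 14.80 ± 0.02 in doxycycline and 16.10 ± 0.27 in untreated cells, a log2 difference of -1.30 (SE 0.19, limma adjusted p = 0.0813). ZDHHC11, of the palmitoyltransferase family, was higher by 0.99 (SE 0.16, limma adjusted p = 0.0839). RAC3, a Rho family GTPase that acts on the actin cytoskeleton, had a log2 difference of -0.94 (SE 0.16, limma adjusted p = 0.0865). FAM72D, ZDHHC11 and RAC3 passed with limma among probes detected on all 4 arrays, with adjusted p of 0.0251, 0.0293 and 0.0307. With limma-trend all 4 genes passed, at adjusted p of 0.0112 for GTF2IRD2, 0.0150 for FAM72D, 0.0279 for ZDHHC11 and 0.0221 for RAC3. Over the limma alternatives in which each was tested, the adjusted p of these genes ranged from 0.0112 to 0.263. GTF2IRD2 was not tested among probes detected on all 4 arrays, and in each gene both doxycycline arrays lay on the same side of both untreated arrays.

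In all, 82 genes could be named among the tested probes, and 19 of them had an unadjusted p under 0.05, 10 higher and 9 lower, where chance gives 4.1. Over all tested probes 5012 of 21167 had such a p, a similar share, so the count is not particular to the nameable genes. Adjusted over these 82 genes alone, GTF2IRD2 passed (limma adjusted p = 0.0172). Identifiers set these genes apart among the tested probes, but the detection filter and the choice of the brightest probe used their signals. GTF2IRD2 was tested only because it was detected on both doxycycline arrays, the group where it was higher. FAM72D, ZDHHC11 and RAC3 each stood at 0.0536. This adjustment was not planned, and no alternative setting was run with it. Over all tested probes GTF2IRD2 did not pass (limma adjusted p = 0.0794). The other 15 genes, none past the adjusted threshold in limma, had smaller differences than these, with the exception of KRTAP19-7. Higher in both doxycycline arrays were NAIP, an inhibitor of apoptosis family protein (log2 difference 0.60, SE 0.18), KLC2, a kinesin light chain (0.64, SE 0.21), and PML, the scaffold of nuclear bodies (0.52, SE 0.16). PML was detected on 1 doxycycline array. LCMT2, which takes part in tRNA modification, differed by 0.48 (SE 0.16), and the histone gene H3C14 by 0.40 (SE 0.15). NOTCH2NLA differed by 0.58 (SE 0.16) on its brighter probe and by 0.11 on its other probe. Lower in both doxycycline arrays were CEP170, a centrosome protein (log2 difference -0.51, SE 0.14), SYT15, a synaptotagmin (-0.84, SE 0.23), and RXFP4, a relaxin family peptide receptor (-0.62, SE 0.19). SYT15 was detected on 1 doxycycline array. EBLN2, SERF1A and ANKRD36B had differences of -0.53 (SE 0.14), -0.39 (SE 0.14) and -0.59 (SE 0.22). Without untreated replicate 1 the difference was 0.40 for KLC2 and -0.33 for ANKRD36B.

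**Figure D2:**
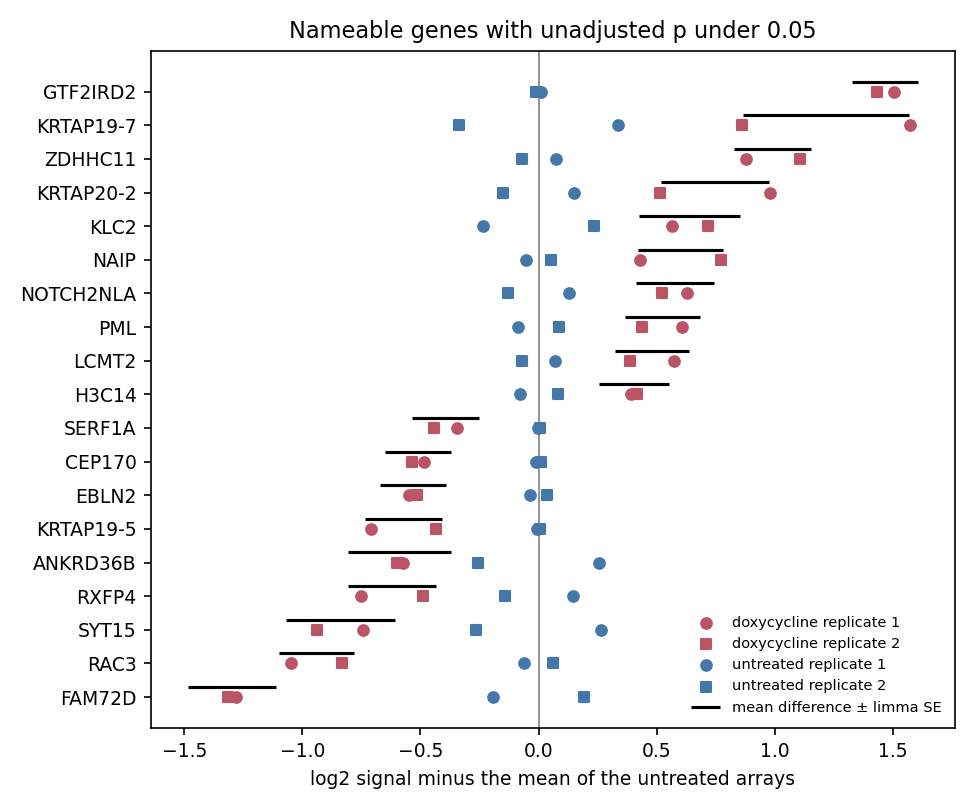
Log2 signal of the 19 nameable genes with unadjusted p under 0.05 on each array, relative to the mean of the untreated arrays (x axis); red marks doxycycline, blue untreated, circles replicate 1, squares replicate 2, and black lines the mean difference ± its limma standard error. Differences run from -1.30 for FAM72D to 1.47 for GTF2IRD2, which was not detected in untreated cells.

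Other nameable genes were not detected on either array of 1 treatment. KRTAP19-7 was not detected in untreated cells and was 2.32-fold higher in doxycycline (limma adjusted p = 0.143). The reverse held for IFNE, a type I interferon, 2.47-fold lower in doxycycline (limma adjusted p = 0.258). It also held for MMP23B, a matrix metalloproteinase, 1.78-fold lower (0.218), and for TET3, a 5-methylcytosine dioxygenase, 1.55-fold lower (0.239). These folds are estimates from undetected signals and depended on single arrays. For IFNE the fold was 1.47 without doxycycline replicate 2 and 4.17 without doxycycline replicate 1. For TET3 it was 1.23-fold without doxycycline replicate 1 and 1.94-fold without doxycycline replicate 2, and for MMP23B 1.44-fold without doxycycline replicate 1 and 1.42-fold without untreated replicate 2. Over all probes, 304 were detected on both doxycycline arrays and neither untreated array, and 387 the other way round. The split by replicate number gave 213 and 231 such probes, and the crossed split 307 and 123.

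Some nameable genes with bright signals, chosen after their values were seen, showed small differences. They do not stand for abundant transcripts as a group. Other bright genes had log2 differences of 0.27 (CEP19), 0.58 (NOTCH2NLA, brighter probe) and -0.01 (NOMO2). ACTG1, cytoskeletal gamma actin, was at 20.57 ± 0.07 in doxycycline and 20.67 ± 0.08 in untreated cells (log2, SD, n = 2), a difference of -0.10 (SE 0.14). GTF2I, another TFII-I family gene, differed by 0.12 (SE 0.15), and CENPX, a centromere and DNA repair protein, by 0.11 (SE 0.15). S100A14, an epithelial calcium-binding protein, differed by -0.16 (SE 0.29). None of these passed the limma test, and their differences depended on the scaling. With median scaling of raw signals they were -0.0012 for ACTG1, 0.29 for GTF2I, 0.01 for CENPX and -0.03 for S100A14. CENPX turned to -0.0072 with the value table as deposited, but stood at 0.11 with the columns of doxycycline replicate 2 exchanged.

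Among identifiers with no symbol, those with the smallest p each way among probes detected on all 4 arrays were chosen after their values were seen. hCG1727099.1 was higher by 2.72 (SE 0.14) and hCG40171.2 by 2.61 (SE 0.15) on the log2 scale, while hCG23755.3 had a difference of -2.86 (SE 0.20) and hCG27799.3 one of -2.45 (SE 0.18). All 4 had a limma adjusted p of 0.0794, and all 4 passed with limma-trend and among probes detected on all 4 arrays. GTF2IRD2, FAM72D, NOTCH2NLA, NAIP, SERF1A, ZDHHC11 and ANKRD36B are among the named genes with close copies in the genome. Signal on their probes can include those copies, and the list may not be complete.

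More probes had an unadjusted p under 0.05 between doxycycline and untreated cells than chance gives on average, but no single probe passed the adjusted threshold. In the limma test 0 of 21167 probes had an adjusted p under 0.05, and the smallest adjusted p was 0.0794. At an unadjusted p under 0.05 there were 5012 probes, 2619 higher and 2393 lower in doxycycline, where chance alone gives 1058. The same count was 405 when the arrays were split by replicate number and 357 for the remaining, crossed split. Both splits carry the treatment difference in their residuals, which lowers their counts, so they do not show what chance gives. A log2 difference of at least 1 between the treatment means was seen on 1354 probes, 695 higher and 659 lower, against 359 and 361 in the other splits. Treated and untreated signals did not overlap on 12172 probes, 57.5%. For a single probe with the arrays in random order the probability is 33.3%. Probes are not independent replicates, so 33.3% does not show what chance gives for the count. No conclusion is drawn from the share without overlap. The files give no slide, date or labelling batch, so a batch that follows the treatment cannot be told apart from it.

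The adjusted count depended on the probes tested and the variance model. Among the 17964 probes detected on all 4 arrays, 1384 passed an adjusted p under 0.05 (702 higher, 682 lower, limma). With limma-trend on all tested probes 1908 passed (987 higher, 921 lower), and 1271 probes were called in both. The count at an unadjusted p under 0.05 was 3278 without untreated replicate 1, in place of 5012. The balance of directions moved with the scaling. Of the probes at an unadjusted p under 0.05, 52.3% were higher in doxycycline after quantile normalization and 63.0% after median scaling of raw signals. The share was 32.9% with the value table as deposited, but 52.4% with the columns of doxycycline replicate 2 exchanged. As deposited, the value table moved the median log2 difference of all tested probes to -0.11.

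**Figure D3:**
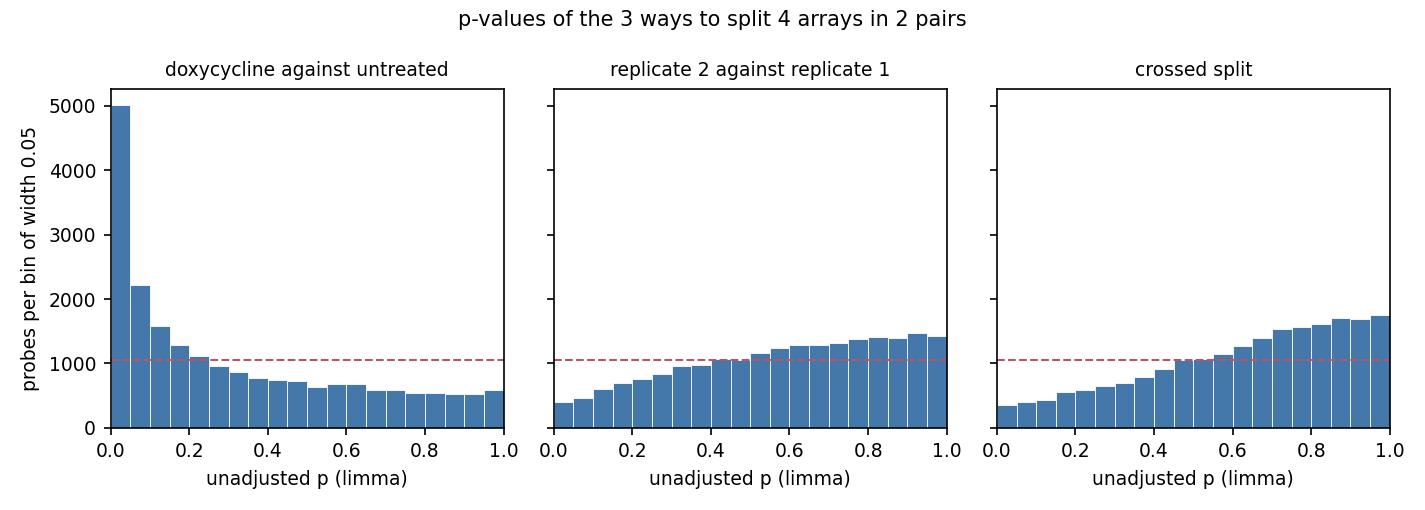
Histograms of unadjusted limma p-values (x axis, bins of width 0.05) over 21167 probes (y axis, probes per bin) for the 3 ways to split the 4 arrays in 2 pairs; the dashed line is the 1058 probes per bin that chance gives. The lowest bin holds 5012 probes for the treatment split, 405 for replicate number and 357 for the crossed split. The latter splits carry the treatment difference in their residuals, which lowers their counts.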

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

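The settings named here as chosen after seeing the data are the value table with the columns of doxycycline replicate 2 exchanged, median scaling of raw signals, the probes above the median of mean signal, and the minimum change added to other settings. The adjustment over the nameable genes alone was not planned either. The count of 0 probes at an adjusted p under 0.05 (limma) stayed at 0 with median scaling, either value table, no detection filter and any array left out. It became 7 with normexp background correction, 1 with the plain two-sample test, 1384 among probes detected on all 4 arrays, 1908 with limma-trend and 1349 among probes above the median of mean signal. For the probes detected on all 4 arrays, 2 causes were tested and are given with the other observations; for the other settings the cause was not tested. With a log2 change of at least 1 besides, 586 probes passed among those detected on all 4 arrays and 732 with limma-trend. The 5012 probes at an unadjusted p under 0.05 became 1143 with that minimum change and 3278 to 4267 with 1 array left out, lowest without untreated replicate 1; the lone array of a group is then assumed to vary like the other group. The labels give same-numbered arrays only a number in common, and a shared clone was not decided; their deviations from the group means correlated at 0.0313. With the replicate block 4872 probes had an unadjusted p under 0.05 and 0 passed. The excess of within-treatment over between-treatment correlation, 0.0124, was 0.00706 over all probes without a detection filter. Of the values of the 4 identifiers, the genes chosen by the rule and those at an unadjusted p under 0.05, 325 kept their side of the threshold and 24 passed it. Only scaling and background correction could turn their direction, since the other settings reuse the same difference or leave out an array from groups that do not overlap, and 0 turned. Outside these, CENPX turned only with the value table as deposited, among the scalings tried. Some keratin-associated protein genes turned with that table or with median scaling of raw signals. The gene list tests and their alternatives were not run, since no list could be formed. A gene near background is limited by signal: probes detected on 2 or 3 arrays had 7.59 times the residual variance of those detected on all 4.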

Other observations

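The tests of the exchanged columns, of a single deviating array and of the deposit error were chosen only after the result was seen. Small gene families could be read from the nameable probes. The 11 tested keratin-associated protein genes (hair shaft proteins) went both ways, 4 higher and 7 lower in doxycycline. Log2 differences ran from -0.57 for KRTAP19-5 to 1.22 for KRTAP19-7, which was not detected in untreated cells. With the value table as deposited 3 were higher, and with median scaling of raw signals 5. KRTAP20-2 differed by 0.75 (SE 0.23), and the smallest limma adjusted p in the family was 0.142. The 3 histone genes H3C14, H4C14 and H1-7 were each higher in doxycycline, by 0.40, 0.32 and 0.30, and stayed higher under each scaling. The smallest limma adjusted p among them was that of H3C14, which did not pass. Both families were picked after the values were seen.

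The own-file signals of doxycycline replicate 2, headed as raw, had the normalized distribution. The median difference of its sorted signals from the mean of the sorted raw columns was 0%, against at least 2.44% for the own files of the other arrays, so raw and normalized columns exchanged at deposit is the candidate explanation. A reader who takes the value table as it stands gets 1449 probes higher and 2957 lower at an unadjusted p under 0.05, where the table with the columns exchanged gives 2633 and 2396. No biological explanation was tested for this pattern.

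More probes had an unadjusted p under 0.05 between the treatments (5012) than in the other splits, whose highest count was 405. The other splits carry the treatment difference in their residuals, which lowers their counts. Whether a single deviating array accounts for it was not decided. The counts with an array left out were set against that highest count of 405. It lies below the 1058 probes that chance gives, so exceeding it excludes nothing. The 5029 probes found with the exchange put right decide nothing about the seemingly exchanged columns, because quantile normalization starts from ranks and both columns rank all probes alike. With 3 splits in all, no share under 0.05 can be reached. A culture, labelling or hybridization batch that follows the treatment cannot be told apart from the drug, because 0 batch columns were given. An effect of doxycycline, through the regulator or not, a single deviating array and a batch all remain open.

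Probes passed the adjusted threshold among those detected on all 4 arrays (1384) and not among all tested (0). Fewer tests in the adjustment do not account for it: the p-values of the fit to all tested probes, adjusted over the smaller set, gave 0 calls. Noise of dim probes in the shared variance estimate may account for it, since the residual variance was 7.59 times higher for probes detected on 2 or 3 arrays (median 0.181 against 0.0239). No biological explanation was tested for this pattern.

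The series text names clones without tying arrays to them, which leaves the hypothesis that same-numbered arrays share a clone. If so, probes whose replicates differ by a log2 of at least 1 in both treatments would mostly differ the same way. Of 21 such probes detected on all 4 arrays, 10 did, or 47.6% (95% exact binomial interval 25.7% to 70.2%). The interval treats probes as independent, which they are not. The probes are too few to decide whether same-numbered arrays share a clone.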
